A study of Homo sapiens with 6 samples.

How the data were processed

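RNA-seq of HCT15 cells was deposited as 1 table of FPKM values for 6 libraries, 3 with a control guide and 3 labelled RBM15 knockout. Per the labels' protocols, cells were grown in RPMI-1640 with serum, RNA was extracted with TRIzol, libraries were built with the VAHTS Universal V6 kit, and paired-end reads of 150 bp were sequenced on an Illumina NovaSeq. Per the submitters' processing notes, HISAT2 2.2.1 and StringTie 2.0.4 were used with the hg38 build. The authors deposited FPKM, fragments scaled by transcript length and by the mapped total of the library, per the file headers and the labels' descriptions. The settings of those tools, the annotation, the use of strand, the selection of RNA and the filter that left the listed rows are not given in the sources used here. Each column was matched to its library by its name, and groups were taken from the titles and genotype labels.

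The table held 12793 rows, of which 12290 carried an Ensembl gene identifier and 503 a locus name made by StringTie, and 672 had no gene symbol. By gene identifier 12220 rows matched GENCODE 29 on GRCh38, and 12199 of these were protein-coding. By gene symbol, 0 genes of the mitochondrial chromosome were listed, so they were not analysed here. Exons of 3253 rows overlapped those of another listed gene. Coordinates are from GENCODE 29. FPKM are already scaled by the mapped total of each library, so column sums are not library depths. Low values were searched for the steps that whole reads would leave: at most 0.93% of the ratios between libraries of values below 0.5 FPKM fell within any window 0.1% wide, so reads were not recovered. Depth per library is therefore unknown, no counting interval is given, and precision rests on the spread between 3 libraries per group. FPKM estimates divide reads between overlapping genes and similar copies, so values of such genes depend on that division.

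FPKM are not counts, so the test was run on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries entered, 11451 in all. limma 3.58.1 in R 4.3.3 fitted the 2 groups without covariates, with moderated variances that followed a trend over the mean level. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Differences on the log2(FPKM + 1) scale understate the change of low genes, and "at least 2-fold" means a difference of at least 1 on that scale. RBM15 and FH were also tested with an exact 2-sided permutation test of their FPKM over the 20 assignments of the libraries. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

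The tests, 41 gene and marker lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined. Of the lists, 34 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation for each list was the alternative, which also takes its degrees of freedom from the libraries. fry was run beside it and its values are not printed. For each list the number of changed members was also computed with p-values adjusted over the list alone. Several lists entered only in part: 8 of 67 replication-dependent histones, 11 of 29 mesenchymal genes and 4 of 28 enterocyte genes were tested. The other listed genes were not in the table or fell below the filter. Another 5 lists were added after the data were seen and are reported only among the closing observations.

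The rule for named genes took RBM15 and FH always, then the 10 largest increases and 10 largest decreases among genes with a symbol, adjusted p of at most 0.05, at least 5 FPKM in the higher group and no overlap between the values of the groups. For each list it took up to 4 changed members with the largest difference, of which the text leaves out some (1 tested list and some of these genes are not reported here); a list with no changed member could have its 2 most abundant named. CD14, EIF4A1, SENP3, ATF4 and the genes named from the added lists were chosen after their values were seen.

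The fit was tested on simulated data for 3 against 3 libraries, with 11380 genes in the step. Of the genes changed by 1.5-fold 79.1% were called, of those changed by 2-fold 95.5% and of those changed by 4-fold 98.5%, and 6 of 11251 unchanged genes were called. All 5 lists shifted by 0.3 on the log2 scale and 0 of 25 unshifted lists were called. Genes were simulated as independent of each other, so list calls under correlation between genes were not tested. Far fewer genes were changed in the simulation than were called in the data. The alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, each library rescaled to a common sum (TPM scale), median centring, quantile normalization, no variance trend, the replicate number as a block and leaving out each library in turn. Added after the data were seen were the removal of a trend with GC content, transcript length and level from each library, and leaving out genes whose exons overlap another listed gene. Every column of per-sample values was used.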

Results

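RNA was measured in 6 libraries of HCT15, an established human colorectal cancer cell line. A control guide was used in 3 libraries, and the other 3 were labelled as RBM15 knockout made with CRISPR/Cas9, which cuts DNA at a guide-directed site. RBM15 is an RNA-binding protein of the complex that writes the m6A mark on RNA. The comparison asked what losing RBM15 inside the tumour cells did to their transcripts, with metabolism and the immune response named as the interest of the study. The deposited table held FPKM for 12793 rows. Its columns summed to between 402288 and 415057 FPKM, and the median row lay between 10.2 and 10.6 FPKM in every library. Read totals were not recoverable from the values, so the depth behind each value is unknown. Log2 levels correlated at 0.992 to 0.993 across genes within a group and at 0.976 to 0.978 between groups, and no pair of libraries shared an identical column. Values below are mean FPKM ± SD of 3 libraries per group. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

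RBM15, the targeted gene, was higher, not lower, in the libraries labelled RBM15 knockout. It stood at 5.97, 5.89 and 5.51 FPKM in control libraries 1 to 3, and at 17.3, 18.5 and 18.03 FPKM in the libraries labelled knockout 1 to 3. The means were 5.79 ± 0.242 and 17.9 ± 0.615 FPKM, a ratio of 3.1. The log2 difference was 1.48 (SE 0.049, limma adjusted p = 3.88e-06), and the exact 2-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it can give. RBM15 (ENSG00000162775) lies on the plus strand of chromosome 1 at 110338506 to 110346681 in GRCh38, and the antisense gene RBM15-AS1 covers 666 bp of its 5′ end. The labels give no guide position, and whether reads were counted by strand is not given in the sources used here. Insertions and deletions made by Cas9 need not lower an mRNA, so the higher RBM15 mRNA does not show that the label is wrong. Nor does it show that the label is right. Each direction below rests on the labels alone: "rose" and "fell" mean higher and lower in the libraries labelled knockout than in the control libraries.

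**Figure D1:**
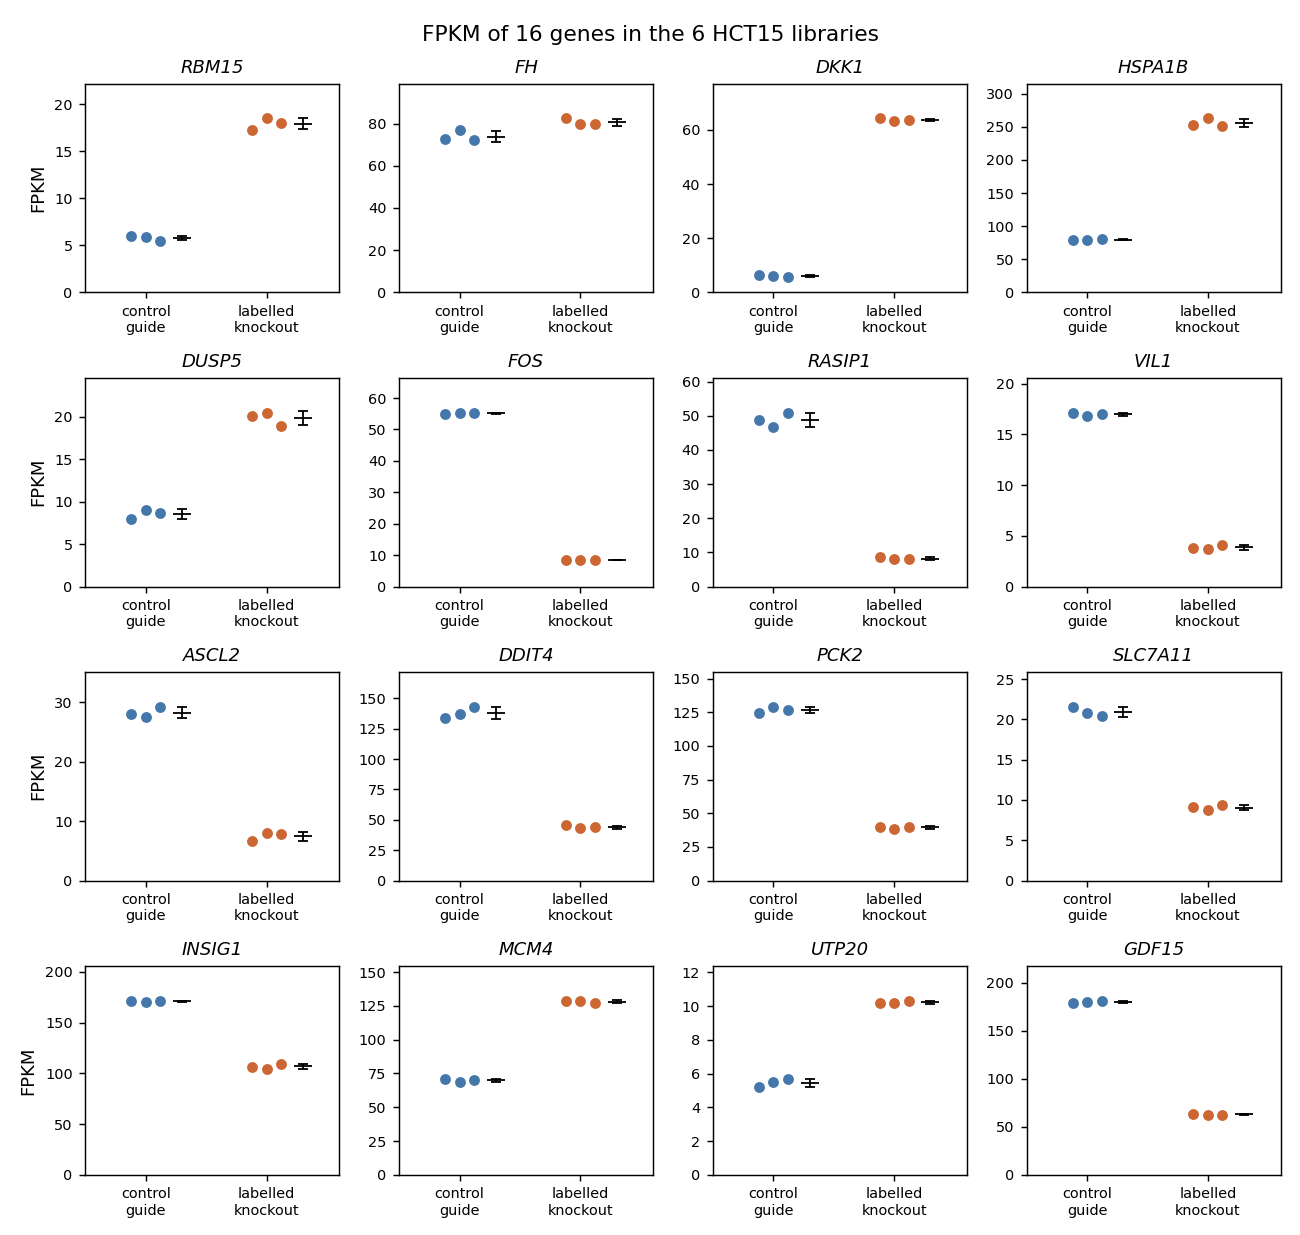
FPKM (vertical axes, linear, from 0) of 16 genes in the 3 control guide libraries (blue points) and the 3 libraries labelled RBM15 knockout (orange points), with the mean and SD of each group in black beside the points. RBM15 rose from 5.79 to 17.9 FPKM and DKK1 from 6.05 to 63.6 FPKM, while FOS fell from 55.1 to 8.41 FPKM.

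DKK1, which encodes a secreted inhibitor of Wnt signalling, had the largest increase among the genes named by rule, from 6.05 ± 0.328 to 63.6 ± 0.537 FPKM in the libraries labelled knockout. DKK1 (ENSG00000107984) lies on chromosome 10 at 52314296 to 52318042. Its log2 difference was 3.20 (SE 0.044, adjusted p = 1.46e-07). The heat-inducible chaperone genes HSPA1B (79.7 ± 0.516 to 256 ± 6.05 FPKM) and HSPA1A (45.8 ± 1.21 to 147 ± 2.22 FPKM) rose, though these near-identical copies share reads and their division between the pair is uncertain. HSPH1, another chaperone gene, rose by 1.09 on the log2 scale, and so did the kinase anchor gene AKAP12 by 1.42, the natural killer cell ligand gene NCR3LG1 by 1.21 and the ERK phosphatase gene DUSP5 by 1.12. The keratin-associated protein gene KRTAP3-1 rose from 3.44 ± 1.14 to 23.7 ± 3.52 FPKM. RBM15 itself was among the 10 largest increases.

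The immediate early transcription factor genes FOS (55.1 ± 0.259 to 8.41 ± 0.0257 FPKM) and FOSB (11.4 ± 0.509 to 1.14 ± 0.172 FPKM) fell in the libraries labelled knockout. FOS (ENSG00000170345) lies on chromosome 14 at 75278774 to 75282230, and its log2 difference was -2.58 (SE 0.032, adjusted p = 1.38e-07). RASIP1, which encodes a Ras-interacting protein, fell from 48.8 ± 2.1 to 8.21 ± 0.311 FPKM, and the glucocorticoid-inducible gene TSC22D3 fell from 27.8 ± 1.28 to 6.67 ± 0.887 FPKM. VIL1, which encodes the microvillus protein villin, fell by 1.89 on the log2 scale. The intestinal stem cell transcription factor gene ASCL2 fell by 1.79, PIP5KL1 by 1.84, the NADPH oxidase activator gene NOXA1 by 1.79 and PRAP1 by 1.77.

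Both remaining genes of the rule carried a wide spread. SENP3-EIF4A1, a read-through gene whose exons overlap those of EIF4A1 and SENP3, stood at 3.44, 21.5 and 20.5 FPKM in the controls and at 189, 44.8 and 35.5 FPKM in the libraries labelled knockout. Its log2 difference of 2.40 (adjusted p = 0.04) became 1.66 without knockout library 1, 2.69 without knockout library 2 and 1.63 without control library 1, and each time the call was lost, as it was without a variance trend (adjusted p = 0.0533) and with a replicate block (0.0898). BEST1, which overlaps FTH1, stood near 38.1 FPKM in the controls and at 22.3, 0.75 and 0.84 FPKM in the libraries labelled knockout. Its call (log2 difference -3.21, adjusted p = 0.0233) was lost when any of the 6 libraries but knockout library 1 was left out. The difference was -4.44 without that library and between -3.23 and -2.58 without any other.

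Over all genes, 6245 of the 11451 tested (54.5%) changed at adjusted p of 0.05, with 2896 higher and 3349 lower in the libraries labelled knockout. Counts of changed members in the lists below are to be read against that share of 54.5%. Many differences were small: 2063 of the changed genes differed by less than 1.2-fold, and 186 differed by at least 2-fold on the log2(FPKM + 1) scale, 33 of them higher and 153 lower. The 3 values of each group did not overlap for 7212 genes (63%), where chance gives 10%. The median log2 difference of all tested genes was -0.018, and the median SD within a group was 0.073. Which direction held more genes depended on scaling, since quantile normalization gave 3367 higher and 2894 lower. The count at 2-fold was 401 with a pseudocount of 0.1, 346 with each library rescaled to a common sum (TPM scale) and 116 with a filter at a mean FPKM of 5.

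**Figure D2:**
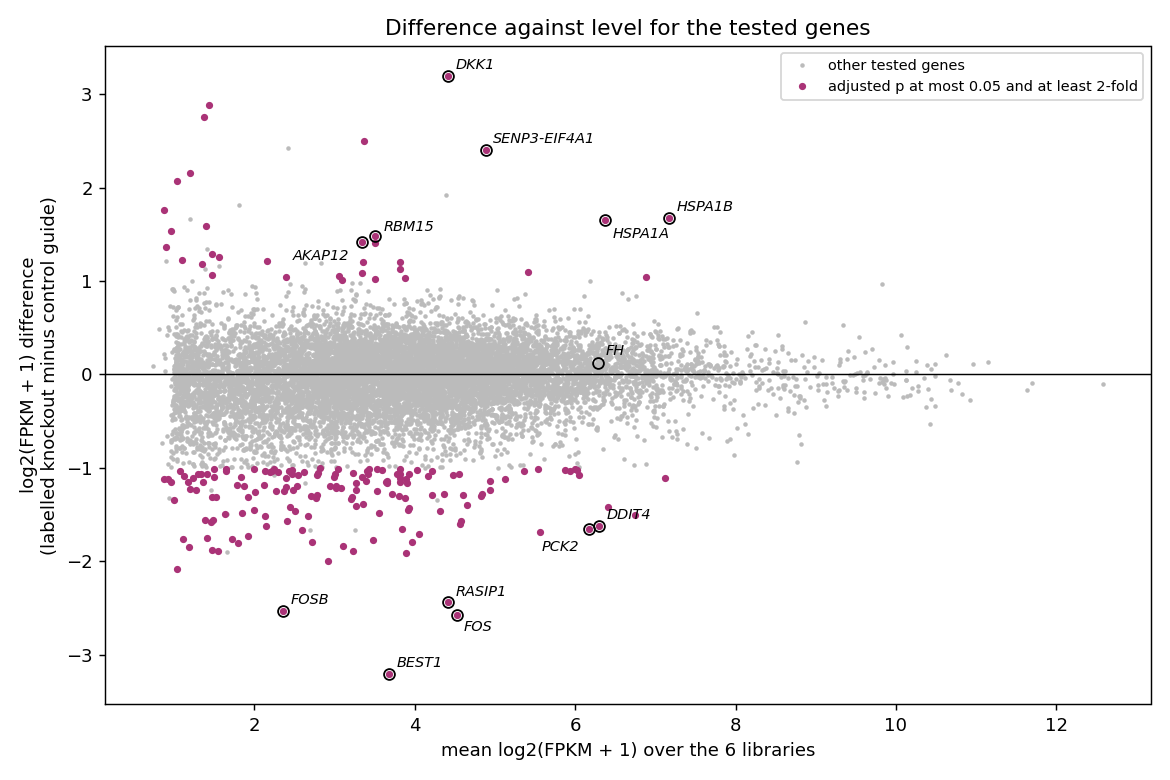
Difference of log2(FPKM + 1) between the libraries labelled RBM15 knockout and the control guide libraries (vertical axis) against the mean log2(FPKM + 1) of the 6 libraries (horizontal axis) for the 11451 tested genes. The 186 genes changed by at least 2-fold are purple and include 33 above and 153 below the line at 0; circles mark named genes, SENP3-EIF4A1 and BEST1 with a wide spread within a group.

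All 26 tested genes in the list of targets of ATF4, the transcription factor of the amino acid response, which includes ATF4 itself, fell in the libraries labelled knockout, over all genes and adjusted over the list alone. Their median log2 difference was -0.80 (camera adjusted p = 1.45e-13). The mTORC1 inhibitor gene DDIT4 fell from 138 ± 4.85 to 44.0 ± 1.26 FPKM and the pseudokinase gene TRIB3 from 138 ± 3.64 to 50.8 ± 0.287 FPKM. CEBPB fell from 40.4 ± 1.78 to 12.6 ± 0.562 FPKM and VLDLR by 1.25 on the log2 scale. Among 17 genes of serine, glycine and folate metabolism, 4 rose and 9 fell, and 13 changed adjusted over the list alone (camera adjusted p = 0.0803). PHGDH, the first enzyme of serine synthesis, fell from 163 ± 3.63 to 83.4 ± 1.06 FPKM, and PSAT1, the next enzyme, from 238 ± 0.737 to 138 ± 3.67 FPKM. ALDH1L1 fell by 0.85 on the log2 scale. This list and the ATF4 list share 2 tested genes, PHGDH and PSAT1, so their falls are not separate evidence. The ATF4 list also shares 1 tested gene each with the NRF2 (SLC7A11), hypoxia (DDIT4) and p53 (SESN2) lists below.

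FH, which encodes fumarate hydratase of the tricarboxylic acid cycle, stood at 73.8 ± 2.52 FPKM in the controls and 80.6 ± 1.57 FPKM in the libraries labelled knockout. FH (ENSG00000091483) lies on chromosome 1 at 241497603 to 241519761. The log2 difference was 0.13 (SE 0.035, limma adjusted p = 0.0197), and the exact 2-sided permutation test gave p = 0.1, the smallest it can give. The limma call was lost without control library 1 (0.114), control library 3 (0.109) or knockout library 1 (0.11), and after removal of a GC and length trend (0.074). Of 28 genes of the tricarboxylic acid cycle, 6 rose and 7 fell, with 13 adjusted over the list alone, and the list as a whole did not pass (median log2 difference -0.016, camera adjusted p = 0.796). PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, fell from 127 ± 2.3 to 39.5 ± 0.907 FPKM. The isocitrate dehydrogenase gene IDH1 fell by 0.56 on the log2 scale, the pyruvate carboxylase gene PC fell by 0.46, and IDH3A rose by 0.43. Among 14 genes of fumarate and urea cycle metabolism, 4 rose and 6 fell, with 10 adjusted over the list alone (camera adjusted p = 0.472). There, the aspartate aminotransferase gene GOT1 fell from 74.2 ± 1.12 to 51.9 ± 1.22 FPKM, its mitochondrial counterpart GOT2 rose by 0.27 on the log2 scale, and the argininosuccinate synthase gene ASS1 fell by 0.42.

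Glycolysis genes rose more often than they fell in the libraries labelled knockout, 12 against 5 of 24, with 18 changed adjusted over the list alone. The glucose transporter gene SLC2A1 rose from 43.5 ± 1.21 to 61.8 ± 2.32 FPKM and the lactate dehydrogenase gene LDHA from 648 ± 7.12 to 855 ± 68 FPKM. The aldolase gene ALDOC fell by 0.47 on the log2 scale, without a call when control library 2, control library 3, knockout library 1 or knockout library 2 was left out (-0.466 to -0.389) or the GC and length trend was removed (-0.283). The camera call (adjusted p = 0.0323) was lost with an estimated correlation (adjusted p = 0.159 with an estimated correlation). Of 77 nuclear genes of oxidative phosphorylation, 9 rose and 18 fell, and 26 changed adjusted over the list alone (camera adjusted p = 0.534). CYCS, which encodes cytochrome c, rose by 0.45 on the log2 scale and the complex I gene NDUFS8 fell by 0.36. By gene symbol, 0 of the 13 mRNAs encoded in mitochondrial DNA were in the table, so they were not tested. Purine and pyrimidine synthesis had 14 genes that rose and 3 that fell of 24, and 19 changed adjusted over the list alone. PFAS rose by 0.48 on the log2 scale and GMPS, another purine enzyme gene, fell by 0.43. That list's call (camera adjusted p = 0.0147) was lost as well (adjusted p = 0.218 with an estimated correlation).

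Genes of cholesterol synthesis and uptake fell together in the libraries labelled knockout: 21 of 25 fell and 1 rose, with 22 changed adjusted over the list alone. The median log2 difference was -0.40 (camera adjusted p = 4.8e-07). The sterol feedback gene INSIG1 fell from 171 ± 0.633 to 107 ± 2.55 FPKM, and the sterol reductase gene TM7SF2 fell by 0.76 on the log2 scale. In fatty acid synthesis and desaturation 10 genes fell and 1 rose of 19, with 11 adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, fell from 49.6 ± 1.24 to 24.8 ± 0.562 FPKM, the lipid synthesis regulator gene SREBF1 by 0.86 and the stearoyl-CoA desaturase gene SCD by 0.67 on the log2 scale. The call of that list (camera adjusted p = 0.0432) was lost (adjusted p = 0.218 with an estimated correlation), and it was also lost without control library 2 (adjusted p = 0.0887), knockout library 1 (0.0613) or knockout library 2 (0.0612), with a filter at 5 FPKM (0.055), on the TPM scale (0.0671), with median centring (0.0572) and with a replicate block (0.0565). Of 22 genes of fatty acid oxidation, 3 rose and 8 fell, with 10 adjusted over the list alone (camera adjusted p = 0.233). ECI1 fell by 0.58 and ACADVL by 0.34 on the log2 scale.

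Stress-related lists were mixed in the libraries labelled knockout. Of 20 glutathione and NRF2 target genes 6 rose and 10 fell, with 17 adjusted over the list alone (camera adjusted p = 0.534). The cystine transporter gene SLC7A11 fell from 20.9 ± 0.581 to 9.07 ± 0.316 FPKM and the heme oxygenase gene HMOX1 fell by 0.77 on the log2 scale. Hypoxia and HIF targets had 12 genes that fell and 3 that rose of 24, with 15 adjusted over the list alone (camera adjusted p = 0.0948). Among them, VEGFA fell from 43.5 ± 1.32 to 17.1 ± 0.329 FPKM and CA9 from 15.6 ± 0.35 to 5.37 ± 0.489 FPKM. The hypoxia list shares 6 tested genes with the glycolysis list. Of 19 chaperones and factors of the unfolded protein response, 10 rose and 2 fell, with 12 adjusted over the list alone (camera adjusted p = 0.113). XBP1, which encodes a transcription factor of that response, was among the 2 and fell from 133 ± 1.28 to 70.4 ± 0.419 FPKM, while the chaperone gene DNAJB11 rose by 0.25 on the log2 scale.

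Among the immune-related lists, most tested cytokine genes fell in the libraries labelled knockout, though the list call depended on the setting. Of 13 tested chemokines and cytokines, out of 45 in the list, 10 fell and 1 rose, with 12 changed adjusted over the list alone. GDF15, which encodes a stress-induced cytokine, fell from 180 ± 1.04 to 62.7 ± 0.782 FPKM and IL32 from 84.7 ± 2.14 to 46.7 ± 2.48 FPKM. The call (camera adjusted p = 0.00855) was lost in other settings (adjusted p = 0.136 with an estimated correlation, and 0.0623 after removal of the GC and length trend). Of 20 genes of MHC class I presentation 8 fell and 1 rose, with 9 adjusted over the list alone. The list did not pass (median log2 difference -0.15, camera adjusted p = 0.0803), and its median was -0.028 with the GC and length trend removed. TAPBP, which loads peptides, fell from 68.6 ± 0.503 to 47.8 ± 0.467 FPKM. Some members of that list share sequence, and their division of reads is uncertain. Of 4 tested genes of MHC class II presentation, too few for a list test, RFXANK fell by 0.52 and RFXAP by 0.21 on the log2 scale, and the call of RFXAP was lost without control library 1 (-0.203), control library 2 (-0.182), knockout library 2 (-0.178) or knockout library 3 (-0.195), and under quantile normalization (-0.158).

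Interferon response genes changed in both directions, 6 higher and 9 lower of 30 in the libraries labelled knockout, with 15 adjusted over the list alone. Of all tested genes 54.5% changed, so this list held no excess of changed members. MX1 fell from 7.98 ± 0.812 to 4.91 ± 0.255 FPKM and IFI35 fell by 0.62 on the log2 scale. The median log2 difference (0.011, and -0.048 with the GC and length trend removed) and the mean (-0.11) differed in sign, and camera, which pointed down, gave adjusted p = 0.718. Of 12 genes of nucleic acid sensing 4 rose and 2 fell, with 6 adjusted over the list alone (camera adjusted p = 0.472). The RNA editing enzyme gene ADAR rose from 48.1 ± 0.637 to 60.1 ± 0.4 FPKM and the double-stranded RNA kinase gene EIF2AK2 by 0.32 on the log2 scale, while DHX58 fell by 0.42, without a call under quantile normalization (-0.275) or with the GC and length trend removed (-0.149). Of 18 checkpoint genes and ligands of killing receptors, 5 rose and 7 fell, with 13 adjusted over the list alone (camera adjusted p = 0.534). Ligand genes of the receptor NKG2D went apart: ULBP1 fell from 9.29 ± 0.147 to 3.18 ± 0.0992 FPKM, and MICB rose from 11.8 ± 0.866 to 21.3 ± 0.982 FPKM. Of 14 NF-kB targets, 5 rose and 5 fell, with 12 adjusted over the list alone (camera adjusted p = 0.868). Their median (0.13) and mean (-0.076) differed in sign, and the direction of the list test turned with other filters. LCN2 fell by 1.46 and ICAM1 by 0.57 on the log2 scale, while SOD2 rose by 0.58.

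Genes of DNA replication and MYC targets rose in the libraries labelled knockout. Of 44 genes of S phase and DNA replication 34 rose and 1 fell, with 35 changed adjusted over the list alone (median log2 difference 0.36, camera adjusted p = 3.67e-11). The replicative helicase gene MCM4 rose from 69.9 ± 1.22 to 128 ± 0.863 FPKM, the cyclin gene CCNE1 from 10.4 ± 0.373 to 18.3 ± 0.309 FPKM and MCM10 by 0.77 on the log2 scale. Of 30 genes in the list of MYC targets, MYC itself included, 27 rose and 1 fell, with 28 adjusted over the list alone (median log2 difference 0.42, camera adjusted p = 7.92e-10). Among them UTP20, which acts in ribosome assembly, rose from 5.47 ± 0.239 to 10.2 ± 0.0828 FPKM, and the RNA polymerase I gene POLR1B from 9.29 ± 0.284 to 16.3 ± 0.552 FPKM. Of 42 genes of G2/M and mitosis 28 rose and 2 fell, with 31 adjusted over the list alone. BUB1B rose by 0.63 and MKI67 by 0.58 on the log2 scale. That call (camera adjusted p = 1.52e-06) was lost (adjusted p = 0.108 with an estimated correlation). Of 8 replication-dependent histone genes 4 rose, also adjusted over the list alone (camera adjusted p = 0.177), and these share sequence with other copies.

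Of 78 cytosolic ribosomal protein genes 25 fell and 2 rose in the libraries labelled knockout, with 24 changed adjusted over the list alone. RPL3 fell from 1612 ± 28.4 to 1274 ± 18.6 FPKM and RPL13A by 0.35 on the log2 scale, with many processed copies in the genome that could share their reads. The call (median log2 difference -0.091, camera adjusted p = 0.00855) was lost (adjusted p = 0.705 with an estimated correlation), and also without control library 2 (adjusted p = 0.0531) or knockout library 3 (0.0816). Mitochondrial ribosomal proteins had 18 genes that rose and 16 that fell of 76, with 33 adjusted over the list alone (camera adjusted p = 0.479), and among them MRPL17 rose by 0.49 and MRPS22 fell by 0.43 on the log2 scale. Of 25 p53 targets 6 rose and 8 fell, with 14 adjusted over the list alone (camera adjusted p = 0.543). SESN2, a stress-responsive regulator of mTORC1, fell from 20.03 ± 0.991 to 8.47 ± 0.163 FPKM, and TIGAR rose by 0.52 on the log2 scale. Of 30 apoptosis regulators 6 rose and 9 fell, with 15 adjusted over the list alone (camera adjusted p = 0.888), and camera's direction turned with overlapping genes left out. The BH3-only genes BBC3 and PMAIP1 fell by 0.75 and 0.70 on the log2 scale, and the death receptor gene TNFRSF10A rose by 0.63. The apoptosis and p53 lists share 4 tested genes, BBC3 among them, so their counts are not separate evidence.

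Lists of intestinal and epithelial genes had more members that fell than rose in the libraries labelled knockout. No list call among them held with an estimated correlation. Of 10 tested colorectal epithelium markers 7 fell and 1 rose, with 8 adjusted over the list alone. VIL1 fell from 16.98 ± 0.168 to 3.87 ± 0.222 FPKM, the intestinal cadherin gene CDH17 from 5.24 ± 0.261 to 1.62 ± 0.184 FPKM, the homeobox gene CDX2 from 20.9 ± 0.138 to 9.52 ± 0.254 FPKM and KRT19 from 455 ± 4.5 to 354 ± 5.75 FPKM. The call (camera adjusted p = 0.00558) was lost (adjusted p = 0.128 with an estimated correlation). Of 25 genes of epithelial junctions and identity 15 fell and 6 rose, with 21 adjusted over the list alone. The epithelial transcription factor gene ELF3 fell by 1.30 on the log2 scale, the tight junction gene TJP3 by 1.28 and CLDN3 by 0.73. That call (camera adjusted p = 0.00804) was lost too (adjusted p = 0.128 with an estimated correlation), and the list shares 5 tested genes with the colorectal markers. Of 21 Wnt targets and intestinal stem cell genes 12 fell and 3 rose, with 15 adjusted over the list alone (camera adjusted p = 0.0803). NOTUM, a secreted Wnt inhibitor gene, fell from 9.80 ± 0.249 to 2.77 ± 0.0744 FPKM, opposite to DKK1. Of the 4 tested enterocyte genes VIL1 and HNF4A fell and CA2 rose by 0.48 on the log2 scale. Of 3 tested goblet genes AGR2 fell by 0.58 and MUC1 by 0.37, the latter without a call when any of the knockout libraries was left out (-0.379 to -0.355) or the GC and length trend was removed (-0.156), or under quantile normalization (-0.229). The trend removal also ended the call of HNF4A (-0.297 before, -0.085 after). Both lists were too short for a list test.

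Markers of cells that a cancer line should not hold were few and moved in both directions with the groups. Of 3 tested leukocyte genes CD68 rose from 2.91 ± 0.216 to 6.68 ± 0.632 FPKM in the libraries labelled knockout, CORO1A fell from 43.0 ± 1.06 to 34.4 ± 0.315 FPKM, and CD14 (3.68 ± 0.468 and 4.40 ± 0.936 FPKM) did not pass. Of 3 fibroblast genes, each below 8 FPKM, ACTA2 fell by 0.19 on the log2 scale, and of 2 endothelial genes CLDN5 fell from 1.26 ± 0.13 to 0.803 ± 0.0738 FPKM. With the GC and length trend removed ACTA2 stood at 0.005 and CLDN5 at 0.051 without a call. The call of ACTA2 was also lost when any library but control library 1 was left out (-0.208 to -0.139), on the TPM scale (-0.176), with median centring (-0.157), under quantile normalization (-0.141) and with a replicate block (-0.185), and that of CLDN5 without control library 1, control library 3 or knockout library 1 (-0.304 to -0.296) and under quantile normalization (-0.195). Of 11 genes of mesenchymal transition 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.81). THBS1 rose by 0.71 on the log2 scale, and CCN2 fell by 0.71.

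Of 23 writers, erasers and readers 10 rose and 4 fell in the libraries labelled knockout, with 15 adjusted over the list alone (camera adjusted p = 0.0909). RBM15 itself is not in this list, nor in the list of splicing factors and SPEN-family genes. METTL16, an m6A methyltransferase gene, rose from 8.96 ± 0.634 to 14.4 ± 0.405 FPKM, ZC3H13 by 0.40 and the demethylase gene ALKBH5 by 0.31 on the log2 scale, while ZCCHC4 fell by 0.32. Of 44 splicing factors and SPEN-family genes 19 rose and 9 fell, with 28 adjusted over the list alone. The splicing regulator gene SRSF1 rose from 81.0 ± 11.3 to 144 ± 4.1 FPKM, the kinase gene CLK1 from 30.01 ± 1.69 to 45.9 ± 1.1 FPKM and PRPF8 by 0.51 on the log2 scale. The call (camera adjusted p = 0.0438) was lost (adjusted p = 0.159 with an estimated correlation), and also without control library 2 (adjusted p = 0.0519), knockout library 1 (0.0578) or knockout library 2 (0.059), with a filter at 5 FPKM (0.0905), under quantile normalization (0.161), with the GC and length trend removed (0.18) and with overlapping genes left out (0.0523).

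**Figure D3:**
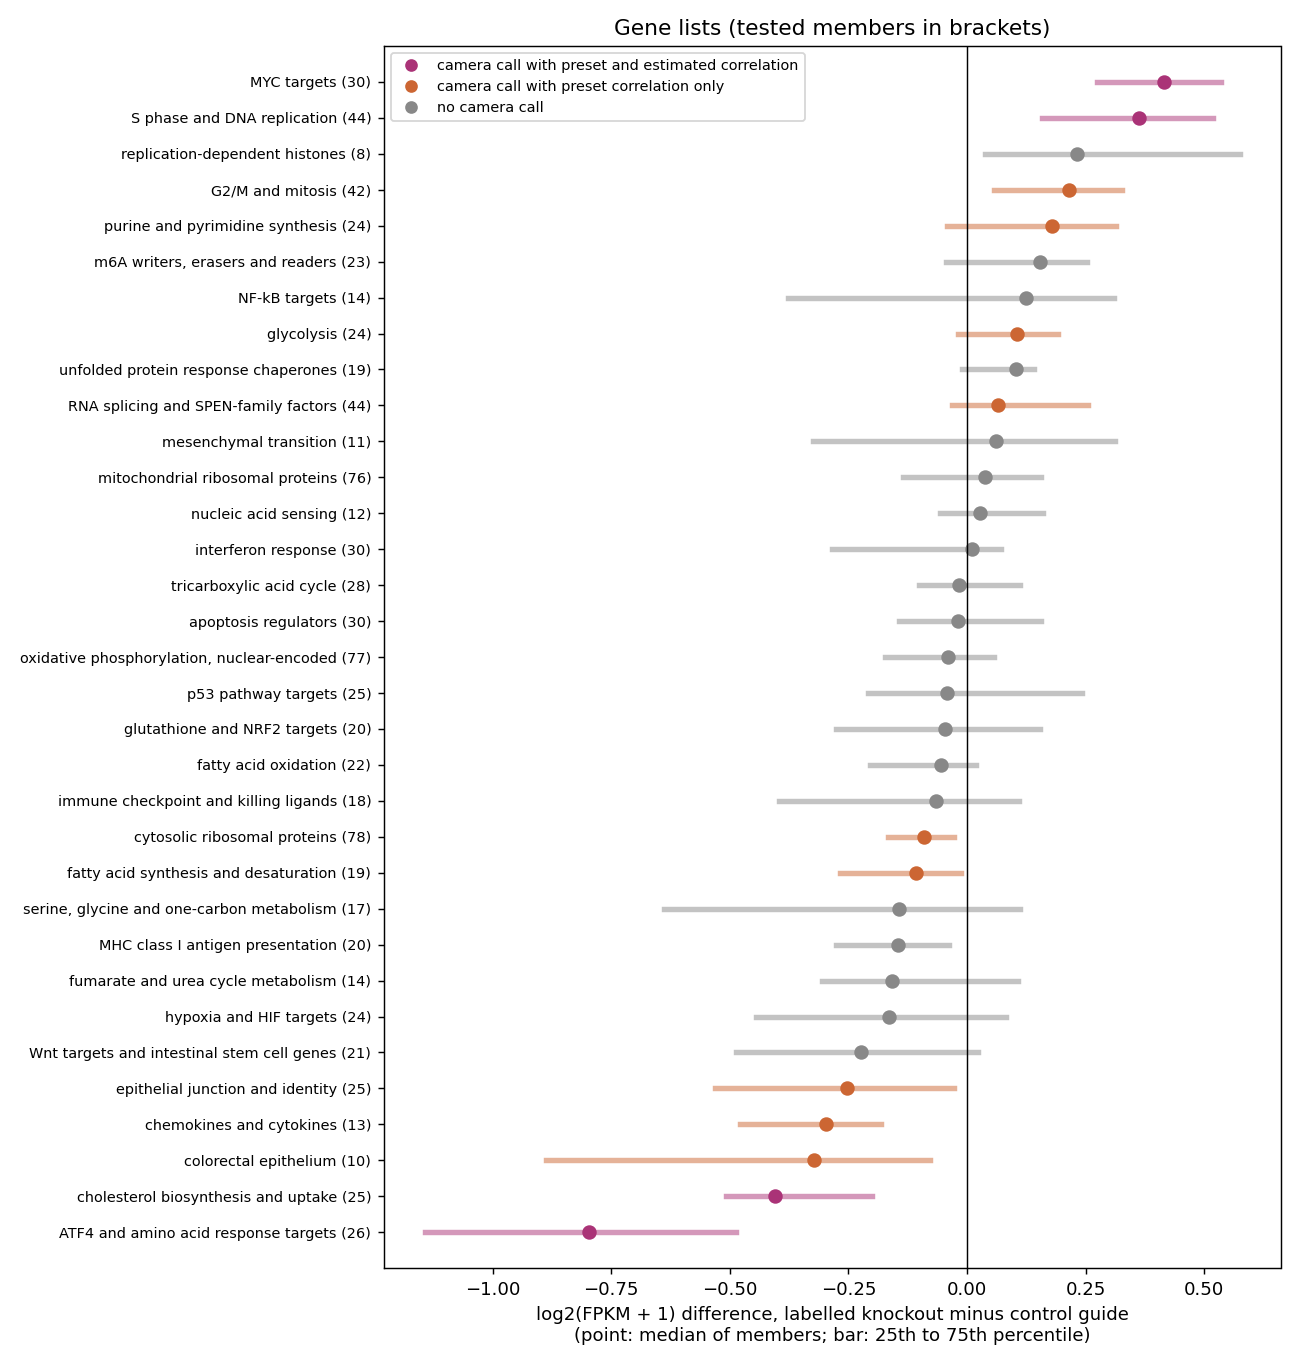
Median difference of log2(FPKM + 1), libraries labelled RBM15 knockout minus control guide, of the tested members of each of 33 of the 34 gene lists (points), with bars from the 25th to the 75th percentile of the members. ATF4 targets lie lowest (median -0.80) and MYC targets highest (0.42); purple lists pass camera with the preset and with an estimated correlation, orange lists with the preset alone.

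In all, 13 of the 34 tested lists passed camera with the preset correlation of 0.01. With an estimated correlation 4 of them held: ATF4 targets (adjusted p = 0.0301), MYC targets (0.0301), S phase (0.032) and cholesterol genes (0.032). That setting also takes its degrees of freedom from the libraries, so a lost call need not mean correlated members. Among lost calls, the estimate was below 0.01 for glycolysis (-0.025), cytokines (-0.049) and splicing factors (-0.009). Epithelial junctions (-0.026) and colorectal markers (-0.062) were below it too. It was above 0.01 for fatty acid synthesis (0.036), purine and pyrimidine synthesis (0.058), G2/M (0.033) and cytosolic ribosomal proteins (0.463). The preset correlation also called 5 to 10 lists in the 9 other splits of the 6 libraries into 3 and 3, each of which mixes the groups and keeps part of any difference between them.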

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

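The tests with the GC and length trend removed, and with overlapping genes left out, were chosen after the data were seen; all others were fixed in advance. RBM15 kept its direction and call under all 16 alternatives (log2 difference 1.45 to 1.615). The number of changed genes ranged from 4758, with overlapping genes left out and 8436 tested, to 6612 with no filter. It was 5451 to 5646 with a library left out. Of the 6245 changed genes, 5728 kept call and direction under quantile normalization, 5283 to 5429 with a library left out, 5040 with the GC and length trend removed (11093 tested) and 4654 with overlapping genes left out. The number changed by at least 2-fold was 401 with a pseudocount of 0.1, which widens differences of low genes, 116 with a filter at 5 FPKM, which tests fewer genes, and 346 on the TPM scale, where low values lie farther above the pseudocount and more genes (12349) pass the filter; these were not separated. FH was 0.074 with the GC and length trend removed and 0.109 to 0.153 with a library left out, and the cause was not tested. Lists passing camera numbered 4 with an estimated correlation and 10 to 15 otherwise, and 4 of the 13 lists kept their call throughout. Splicing factors and fatty acid synthesis each lost it in 8 settings. Genes of serine metabolism passed in 3 settings, and m6A genes (adjusted p = 0.0364) and Wnt targets (0.038) with overlapping genes left out. Replicate numbers were not treated as pairs, as fixed in advance, since no label says that a number marks a shared day or batch. Deviations of same-numbered libraries correlated at -0.035, -0.037 and 0. The fit with a replicate block called 5782 genes and 12 lists. Of 172 named genes besides RBM15 and FH, 152 had the same call in every alternative that tested them. Reversed were ACTA2 (0.005) and CLDN5 (0.051) with the GC and length trend removed, and genes without a call: EIF4A1 under quantile normalization (-0.005) and with a library left out (-0.121 to 0.146), and SENP3 (-0.231 to 0.099). Among the reported lists without a call, the direction turned for NF-kB targets (adjusted p = 0.989 with no filter, 0.866 with a filter at 5 FPKM, 0.93 on the TPM scale) and apoptosis regulators (0.802 with overlapping genes left out). With the GC and length trend removed, the median log2 difference of MHC class I genes went from -0.146 to -0.028, and among the reported lists the sign of the median turned for the interferon response (0.011 to -0.048), p53 targets (-0.043 to 0.036), mesenchymal transition (0.061 to -0.046) and apoptosis regulators (-0.018 to 0.024), all without a call. The cause of these reversals was not tested. Depth is unknown, so the limit it sets on low genes cannot be given.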

Other observations

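Chosen only after their results were seen were the 5 added lists and the genes named from them, ATF4, CD14, EIF4A1 and SENP3 as named genes, the tests of copy gain, of exchanged libraries and of exchanged labels, and the count of splits for all changed genes. In the list of heat shock factor targets 22 of 24 genes rose in the libraries labelled RBM15 knockout and 2 fell, with 24 changed adjusted over the list alone. The median log2 difference was 0.59 (camera adjusted p = 1.34e-11, and adjusted p = 0.0341 with an estimated correlation). HSPB1 fell from 554 ± 9.1 to 354 ± 9.02 FPKM and PTGES3 by 0.109 on the log2 scale. The cochaperone gene DNAJB1 rose from 81.6 ± 2.72 to 169 ± 3.83 FPKM (SD, 3 libraries per group), beside HSPA1A, HSPA1B and HSPH1. The list was written because those genes led the increases, so it is not independent evidence of the direction. Immediate early genes of the serum response went both ways, 7 higher and 12 lower of 23 (camera adjusted p = 0.106). JUN fell from 31.0 ± 0.874 to 12.2 ± 0.486 FPKM and DUSP1 from 9.02 ± 0.487 to 3.76 ± 0.127 FPKM, in addition to FOS and FOSB. Among the 7 that rose, FOSL1 went from 16.6 ± 1.42 to 30.05 ± 2.49 FPKM.

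ATF4, the gene of the transcription factor itself and 1 of the 26 genes of the list named for it, fell from 601 ± 20.9 to 313 ± 13 FPKM in the libraries labelled knockout. Cytosolic aminoacyl-tRNA synthetase genes, many of them ATF4 targets, fell in 13 and rose in 5 of 20 cases, and the list did not pass (camera adjusted p = 0.09), though it did under quantile normalization (adjusted p = 0.0362) and with the GC and length trend removed (0.024). CARS1 fell from 55.6 ± 3.33 to 33.4 ± 1.56 FPKM and SARS1 from 189 ± 3.42 to 123 ± 0.952 FPKM. AARS1, GARS1 and WARS1, which fell, are also in the ATF4 list, so their falls are not separate evidence. Of 17 mitochondrial aminoacyl-tRNA synthetase genes 5 rose and 2 fell (camera adjusted p = 0.499), with LARS2 higher by 0.51 and TARS2 lower by 0.20 on the log2 scale. In the SMN complex and the methylosome, which assemble small nuclear ribonucleoproteins, 7 of 13 genes rose and 1 fell. GEMIN5 rose from 9.31 ± 0.203 to 20.1 ± 0.462 FPKM and GEMIN4 from 8.46 ± 0.256 to 14.4 ± 0.405 FPKM, while GEMIN8 fell from 4.215 ± 0.932 to 2.62 ± 0.0148 FPKM. That list's call (camera adjusted p = 0.0313) was lost in other settings (adjusted p = 0.172 with an estimated correlation, 0.0503 without control library 2, 0.0588 under quantile normalization and 0.0526 with a replicate block).

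RBM15 was higher in the libraries labelled knockout, with a log2 difference of 1.48. A copy gain of the region is argued against by 38 tested genes within 2 Mb on either side, whose median log2 difference was 0.012 (SE 0.047) and of which 0 reached 1; a gain of RBM15 alone was not tested. An exchange of single libraries between the groups is argued against by the correlations, since the lowest within a group was 0.9922 and the highest between groups 0.9783. An exchange of the labels of both whole groups cannot be told apart from an effect of the guide, because the difference of 1.48 in RBM15 is the only value that bears on which group was edited, and under it every direction above would turn. Also open and untested are a feedback of lost RBM15 protein on its own mRNA and reads from RBM15-AS1.

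The ATF4, S phase, MYC and cholesterol lists passed camera with both correlations. A trend with GC content, transcript length or level is argued against as the whole cause, since after its removal from each library the median log2 differences were -0.809, 0.337, 0.449 and -0.411, against -0.797, 0.363, 0.416 and -0.404 before, and each list still passed. Cell density and nutrient state of the cultures were not tested and stay open, since no label gives density or feeding. An effect of the guide stays open as well.

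Among the 186 genes changed by at least 2-fold, 16 had values spanning at least 1 on the log2 scale within a group, SENP3-EIF4A1 and BEST1 among them. A different division of reads between overlapping genes may account for these: 9 of 11 with a GENCODE position (81.8%) overlapped another listed gene, against 39 of 156 (25%) of the other genes changed that far (Fisher's exact test, one-sided p = 0.000249). Low expression went with the pattern as well, at a median of 2.86 FPKM against 8.2 FPKM (ratio 0.35), so the data leave both open. At SENP3-EIF4A1 the overlapping genes EIF4A1 (713 ± 25.1 and 725 ± 133 FPKM, adjusted p = 0.955) and SENP3 (34.9 ± 3.48 and 32.6 ± 8.09 FPKM) did not pass, and both were lowest (593 and 23.3 FPKM) in knockout library 1, where SENP3-EIF4A1 was highest (189 FPKM); at BEST1 the overlapping gene FTH1 fell as well, from 1643 ± 26.4 to 1140 ± 25.8 FPKM (adjusted p = 1.6e-05). No biological explanation was tested for this pattern.

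The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, 6245 genes changed, and the highest count of any other split was 0, with 108 to 142 genes at an unadjusted limma p under 0.05. The real split gave 186 genes changed by at least 2-fold and the others at most 0. It passed 13 lists, and the highest of the others passed 10. Every other split mixes libraries of both groups, so any difference between the groups widens the spread on each side and lowers its gene calls. It also keeps part of that difference, which can raise its list calls. Neither its gene calls nor its list calls are therefore a count for unchanged groups. The counts of 0 genes lend the real split no support.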
